A study of Homo sapiens with 6 samples.

How the data were processed

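Expression was measured on 6 Illumina bead arrays, 1 for each combination of 2 subclones (1E8 and 2B4) of the human prostate cancer line PC-3M and 3 conditions: no added ATP, 100 µM ATP for 6 h and 100 µM ATP for 12 h. Per the labels' protocols, total RNA was isolated with Trizol, cleaned on RNeasy columns, and amplified and biotin-labelled as cRNA with the Illumina TotalPrep kit, which primes from poly(A) tails. Each sample's group was taken from its title. Every group holds 1 array, so no group has a replicate of its own, and precision is limited by the number of arrays.

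The deposited intensity values are linear, with 34594 entries on every array, each named by a gene symbol or a sequence cluster. The software and version behind them are not given in the sources used here. The values themselves show a background subtraction and a common scale: between 24.0% and 25.5% of the entries lay below 0 on each array, and the array means were all between 193 and 194. A further table holds 6 columns of signals that were not normalized, whose names match no sample label, and these columns were not used here. The design fixed before the data were examined called for background correction and quantile normalization of such signals, with detection p-values as the filter. The deposited intensities took their place, and a detection limit was set from each array's own background instead.

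Intensities below 0 were set to 0, and log2(intensity + 16) was used for all tests. Differences are on this log2 scale, which understates the change of dim genes. For each array the peak of the dim values and the width of the distribution below that peak were estimated, and an entry counted as above the limit where it exceeded the peak by 3 widths. The limit was 29.6 on the 1E8 control array, where the background was narrowest with a width of 8.73. On the other 5 arrays the limits lay between 43.8 and 52.6 and the widths between 12.9 and 15.3. Entries above the limit on at least 1 of the 6 arrays were tested. The 3270 entries named by a sequence cluster were left out, and 132 entries that shared a gene with a brighter entry were left out in favour of the brighter one. This left 11095 tested entries, of which 8489 were above the limit on all 6 arrays and 965 on 1 array alone. Of all entry names, 17757 were current symbols and 3303 were unique older synonyms in a RefSeq gene table for GRCh38.p14. The other 13534 matched none and kept the deposited name. No pair of arrays held identical values.

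Differences were tested with limma 3.58.1 in R 4.3.3. An additive model with subclone and condition over all 6 arrays gave the contrasts of ATP (mean of 6 h and 12 h) against control, 6 h against control, 12 h against control, 12 h against 6 h, and 1E8 against 2B4, with 2 residual degrees of freedom. A model with an added term for the ATP effect in 1E8 minus that in 2B4 had 1 residual degree of freedom. The spread of these tests is the departure of the 6 arrays from the model, so p-values measure only the spread between these samples, which may be technical. Benjamini-Hochberg adjusted p under 0.05 was the threshold over the tested entries. The 28 gene lists were fixed before the data were examined. The 24 of them with at least 5 tested genes were tested with camera, at a preset correlation between genes of 0.01 and with an estimated correlation. The estimated form has only the residual degrees of freedom of the fit, 2 or 1 here, while the preset form has far more. A list can thus lose its call in the estimated form without a higher correlation. Camera compares a list with all other genes, so its direction is relative to them. Each ATP array was also set against the control array of its subclone without a test. There a list's median was placed among the medians of 10000 random lists of the same size matched on mean expression, as a description of those arrays. Slide and scan position were not given in the sources used here and were not tested as batches.

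Genes named in the text follow a rule fixed before the data were examined. For ATP these are the 10 highest and 10 lowest genes above the limit on all 6 arrays with the same sign on all 4 ATP arrays, those past the threshold before others. For each time, for 12 h against 6 h, for each array pair and for the interaction they are the 5 highest and 5 lowest. For subclone they are the 10 highest and 10 lowest past the threshold, above the limit on all 6 arrays, with the same sign in all 3 conditions. Added to these are the 5 largest lower bounds each way, up to 4 members of each list, CXCL8 (deposited as IL8), SNAI1, CDH1, CLDN1, the matrix metalloproteinases and the P2 receptors. Placeholder symbols were skipped, and some results that the rule names are not reported here. A gene above the limit on every array of one side and on none of the other has a bound: the bright side's mean over the higher of the dim arrays' limits and values.

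The models were tested on simulated arrays, 20 sets with 200 changed genes among 11095. For the ATP contrast, 83.1% of genes changed by a log2 of 1 were recovered and 4.55% of those changed by 0.5. For subclone the shares were 88.4% and 5.15%, and for ATP at 6 h they were 62.2% and 1.79%. For the interaction, 2.39% were recovered at a log2 of 1 and 49.2% at 2, and 14.9% of its calls were false. Every set also held genes changed by 2, of which 99.1% were recovered for ATP, and such calls ease the adjusted threshold for smaller changes. The data gave 0 calls for ATP, so changes of 1 could be missed there more often than these shares show. In simulated lists shifted by a log2 of 0.3, camera recovered 100% of shifted lists with the preset correlation and 0% with an estimated one, for both ATP and subclone. The simulated noise was independent between genes, while the data gave estimated correlations of up to 0.328, for G2/M genes with ATP. Of the lists called for ATP, cholesterol synthesis (-0.0356), heat shock genes (-0.0285), cancer-testis antigens (-0.0421) and the stress response (0.00825) had estimates under the preset 0.01. The other called lists had estimates above it, such as 0.216 for interferon-stimulated genes. The shift was also larger than the ATP median of any called list, the highest being 0.187 for metastasis suppressors. These simulations therefore do not test the preset correlation. A list not called with an estimated correlation cannot be read as unchanged, since shifted lists of independent simulated genes were not called with it either.

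The alternatives fixed in advance were arrays scaled to 1 median, an offset of 50, a limit passed on at least 3 arrays, no filter on dim entries, the mean of the entries of a gene, a mean-variance trend in limma, each array left out in turn, both times as 1 level, no condition term in the subclone fit, an estimated correlation, and a 1.5-fold threshold for array pairs. Quantile normalization, values floored at 50, a limit passed on all 6 arrays, the highest of the 6 limits on every array (for genes seen on one side alone) and the estimated correlation for the other contrasts were added after seeing the data. Figures were drawn with matplotlib 3.10.9.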

Results

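PC-3M is a metastatic derivative of the human prostate cancer line PC-3, and 1E8 and 2B4 are subclones of it that are known for high and low metastatic capacity. Both were grown without added ATP or with 100 µM ATP for 6 h or 12 h. The labels give no time for the controls, and the control array of each subclone serves both times. Differences from control at 6 h or 12 h, and between these times, therefore cannot be told apart from time in culture. Extracellular ATP activates P2 receptors at the cell surface. The design asks how the transcriptome of each subclone responds to ATP, whether the response differs between times or subclones, and how the subclones differ from each other. Each of the 6 groups had 1 array, and between 9401 and 11237 of the 34594 entries were above the detection limit, the most on the 1E8 control array. Across 11095 tested genes the arrays of one subclone correlated at r of 0.983 to 0.991, and arrays of different subclones at 0.957 to 0.970.

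With ATP, the mucins MUC13 and MUC5AC were higher on all 4 ATP arrays than on the control array of their subclone, by a log2 of 1.42 ± 0.23 and 0.82 ± 0.19 (SE of the fit over 6 arrays). The protease inhibitor SPINK13 (deposited as SPINK5L3) was higher by 1.17 ± 0.13, the retinoic acid-inducible receptor GPRC5A by 1.09 ± 0.19 and the guidance ligand SLIT2 by 0.96 ± 0.17. Of the genes above the limit on all 6 arrays, the Cajal body RNA SCARNA13 had the highest value, 1.63 ± 0.24, and FBN2, IL7R, DHRS9 and HBEGF lay between 0.76 and 0.88. Among the lowest values were those of the ubiquitin ligase RNF165, -1.06 ± 0.18, and the giant scaffold protein AHNAK2, -0.96 ± 0.11. FAR2, the RNA-binding protein SYNCRIP, the nuclear receptor NR2F1, the collagen gene COL1A2, PPP1R10, TRIM9 and RPRML followed at -0.85 to -0.76. None of these passed the threshold: limma called 0 of 11095 genes, with a smallest adjusted p of 0.215, while 350 genes were higher and 782 lower at an unadjusted p under 0.05, against 554.75 by chance. That split depended on the scaling, with 554 higher and 542 lower once arrays were scaled to 1 median and 493 higher and 594 lower after quantile normalization. Without 1 array, limma called 57 genes (without the 2B4 6 h array), 24 (1E8 6 h), 13 (1E8 12 h), 12 (2B4 control), 4 (1E8 control) or 0 (2B4 12 h). Each such fit, here and below, leaves 1 array in a condition that is then fitted exactly and adds nothing to the error. Calls gained in these fits therefore do not count as support for single genes. Single values moved too, with SCARNA13 between 1.09 (without the 2B4 control) and 2.16 (1E8 control) and MUC5AC between 0.44 (1E8 control) and 1.20 (2B4 control), while GPRC5A fell to 0.69 (1E8 control) and PPP1R10 and COL1A2 both came to -0.49 (2B4 control).

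**Figure D1:**
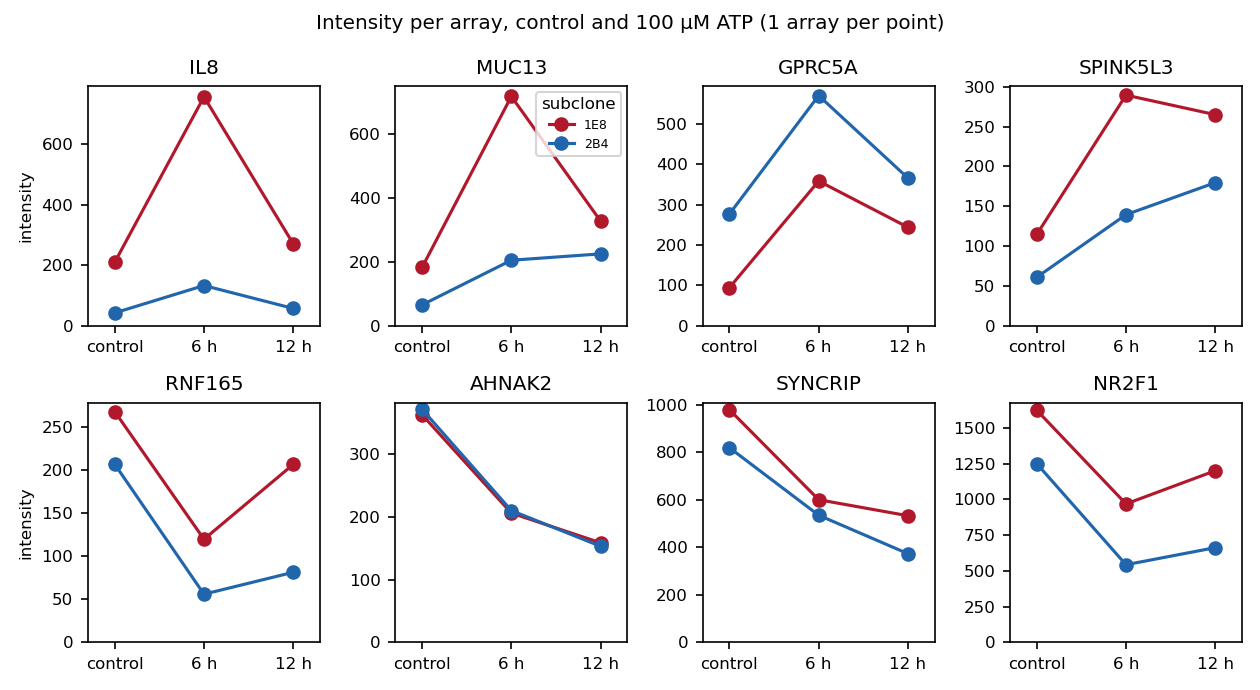
Intensity per array of 8 genes in 1E8 and 2B4 without ATP and after 6 h and 12 h of 100 µM ATP, 1 array per point, on a linear axis from 0. IL8 (CXCL8) went from 210 to 757 at 6 h and 271 at 12 h in 1E8, and AHNAK2 was lower at each later time in both subclones.

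Among the gene lists, cholesterol synthesis stood upward of other genes in the ATP contrast: 17 of its 22 genes had positive values, with a median of 0.14, and camera gave an adjusted p of 0.00211. TM7SF2 was higher by 0.47 ± 0.13 and DHCR7 by 0.31 ± 0.13. The interferon-stimulated genes had the same adjusted p of 0.00211, with 16 of 24 positive and ISG20 at 0.81 and the transcription factor IRF9 at 0.67. The metastasis suppressor list (10 of 13 positive, 0.00483), with CD63 at 0.31, heat shock genes (13 of 18, 0.0125), oxidative phosphorylation (29 of 45, 0.0167), the integrated stress and unfolded protein response (20 of 35, 0.0247), cancer-testis antigens (9 of 11, 0.0247) and G2/M genes (26 of 44, 0.0336) also stood upward. Genes of G1/S and DNA replication stood downward (31 of 39 negative, adjusted p = 0.0292), with UNG at -0.41 and CHAF1A at -0.34. The adjusted p of every one of these 9 lists was 0.563 or higher with an estimated correlation. No single member passed over all genes, and adjusted over the list alone 7 members over the 28 lists were higher and 8 lower. The other 15 lists had adjusted p from 0.0527 to 0.956, and 5 of the 24 tested lists, none of them called, had a median, mean and test that differed in sign. Without either control array 5 lists were called. Cholesterol synthesis kept its call without each array in turn, and each of the other 8 lost it without at least 1. Cancer-testis antigens and G1/S genes lost theirs in 5 of the 6 fits (adjusted p up to 0.194 and 0.222), G2/M genes in 3 (0.673), the stress response (0.505) and oxidative phosphorylation (0.234) in 2, and heat shock genes (0.316), metastasis suppressors (0.146) and interferon-stimulated genes (0.072) in 1. Single members moved, with TM7SF2 between 0.31 (without the 2B4 control) and 0.63 (1E8 control), DHCR7 between 0.15 (1E8 control) and 0.47 (2B4 control), IRF9 at 0.43 (2B4 control) and UNG at -0.27 (1E8 6 h).

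Apart from SCARNA13, short noncoding RNAs were picked after their values were seen. Of 95 such entries tested, 13 were higher on all 4 ATP arrays and 19 lower, the lowest being VTRNA1-2 at -1.07. Of the 13, 10 had an ATP value of at least 0.7. Among these 10 were 7 of the 8 Cajal body RNAs (SCARNA), which guide the modification of spliceosomal RNAs. SNORA12 was higher by 1.60 ± 0.27, SNORA79 by 1.57 ± 0.43, SCARNA16 by 1.03 ± 0.17 and TERC, the RNA template of telomerase, by 0.81 ± 0.12. In 9 of the 10 the response was larger in 2B4, with a median over the 10 of 0.84 in 1E8 and 2.15 in 2B4. On the 2B4 control array only SCARNA13, at 70.8, was above the limit of 52.6. For the others the size of the 2B4 response, and so its rank against 1E8, rests on a control value at background. Without the 2B4 control, which leaves the values of 1E8 alone, SNORA79 was at 0.49, SCARNA18 at 0.78, SNORA12 at 0.97 and SCARNA16 at 0.74. In 5 members (SCARNA8, SCARNA11, SCARNA12, SCARNA14 and SCARNA18) both controls were under the limit, so their log2 values rest on the offset. These 5 were tested only because ATP arrays lay above the limit. The filter thus sets the share of 7 of 8 in part, and SCARNA entries under the limit on every array are not counted. SCARNA11, for example, was at -2.14 in 1E8 and -3.17 in 2B4 without ATP, at 48.9 and 18.2 with ATP in 1E8, and at 76.4 and 71.2 in 2B4. The adjusted p of these 10 in limma was between 0.215 and 0.332, and SCARNA11 was above the limit on 3 arrays. The 37 SNORD entries had a median of -0.17 with 10 lower on all 4 ATP arrays.

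**Figure D2:**
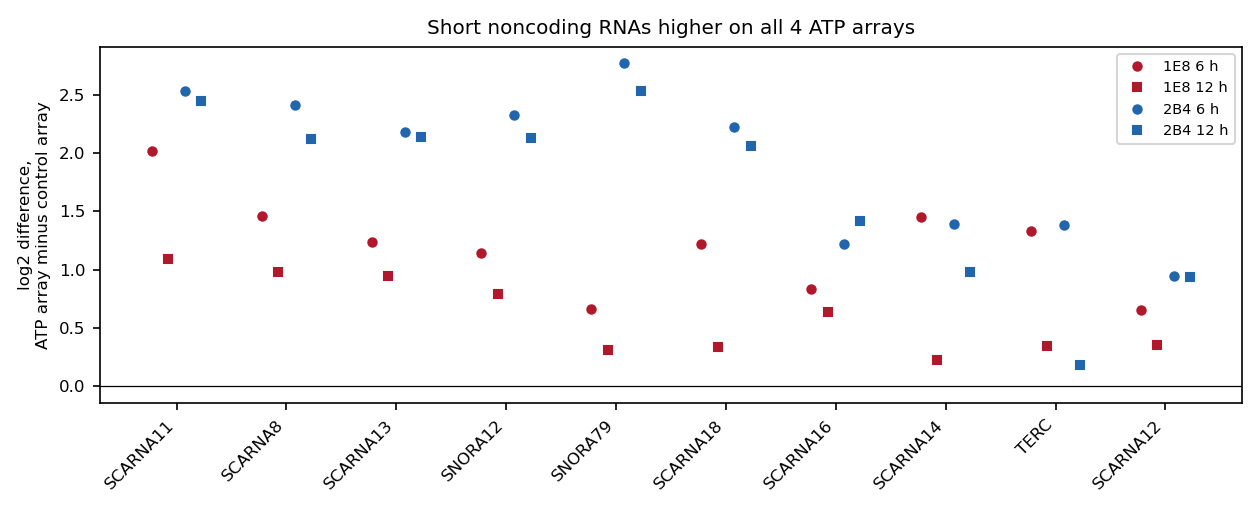
Log2 difference between each ATP array and the control array of its subclone for 10 short noncoding RNAs, with colour for subclone, circles for 6 h and squares for 12 h. All 40 differences lie above 0 by the rule that picked these RNAs, the lowest being that of TERC in 2B4 at 12 h, 0.18.

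At 6 h the chemokine CXCL8 (IL8), which attracts neutrophils, was higher by a log2 of 1.56 ± 0.16, with intensities of 210 in the control and 757 with ATP in 1E8, and 43.1 and 133 in 2B4. The 2B4 control value lay under the limit of that array, 52.6, so the size of the 2B4 change rests on a control at background. Of the genes above the limit on the 4 arrays compared, SCARNA13 (1.71 ± 0.27), MUC13 (1.66 ± 0.27), GPRC5A (1.38) and SLIT2 (1.18) were among the highest, and RNF165 (-1.35), RPRML (-1.15), RAB26 (-1.01) and PRDM8 (-0.99) among the lowest. P2RY11, a G protein-coupled receptor activated by ATP, was at 1.12 ± 0.18 here but negative at 12 h, with 3 of 6 arrays above the limit. Of the heat shock genes 17 of 18 had positive values, with a median of 0.29, CRYAB at 0.63, HSPB8 at 0.43 and HSPA1B at 0.38 (camera adjusted p = 2.76e-06, and 0.536 as the adjusted p with an estimated correlation). G2/M genes stood upward with 32 of 44 positive, AURKA at 0.80 ± 0.13 and PLK1 at 0.49 (0.000501, and 0.666 as the adjusted p with an estimated correlation). On single arrays their 6 h median was -0.01 in 1E8 and 0.23 in 2B4, and the call was lost without the 2B4 6 h array (adjusted p = 0.233) or the 2B4 control (0.134). Immediate early and AP-1 genes (0.0312) stood upward although the phosphatase gene DUSP6 had a negative value (-0.78). Replication-dependent histones stood downward, with 12 of 15 negative and HIST1H2AC at -0.70 (0.0213), as did G1/S genes (0.0301). Upward calls were also given to cholesterol synthesis (0.0156), metastasis suppressors (0.0156), unfolded protein response (0.0213), cancer-testis antigens (0.0301), interferon-stimulated genes (0.0389) and oxidative phosphorylation (0.0438). Of these, the unfolded protein response list had a 6 h median of 0.105 in 1E8 but -0.0493 in 2B4. The interferon list likewise had 0.0946 in 1E8 and -0.00244 in 2B4. For these 11 lists the adjusted p was at least 0.536 with an estimated correlation. The other 13 had adjusted p from 0.0594 to 0.918, and 6 of them had a median, mean and test that differed in sign. Adjusted over the list alone, 8 members over all lists were higher and 10 lower. limma called 0 genes at 6 h, with 357 higher and 732 lower at an unadjusted p under 0.05 (499 and 537 with arrays scaled to 1 median, 479 and 585 after quantile normalization), a smallest adjusted p of 0.161 for CXCL8, and 1 call, CXCL8, with a mean-variance trend (adjusted p = 0.0424). Without 1 array 49 (2B4 6 h), 15 (1E8 6 h), 9 (either 12 h array), 8 (2B4 control) or 5 genes (1E8 control) passed, and 7, 4, 11, 3 or 2 lists in that order. Heat shock genes kept their call without each array in turn. Oxidative phosphorylation lost its call in all 6 fits (adjusted p from 0.058 to 0.351), cancer-testis antigens and metastasis suppressors in 4, the unfolded protein response and G2/M genes in 2, and the other 5 lists in 3, interferon-stimulated genes with an adjusted p of up to 0.666. MUC13 lay between 1.24 (without the 1E8 6 h array) and 2.08 (2B4 6 h), and GPRC5A between 0.98 (1E8 control) and 1.78 (2B4 control), while HSPB8 fell to 0.24 (1E8 6 h) and PLK1 to 0.28 (2B4 6 h).

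At 12 h SCARNA13 (1.55 ± 0.27), SPINK13 (1.22 ± 0.15), MUC13 (1.18 ± 0.27), TELO2 (0.96) and IRF9 (0.93) were highest among the genes above the limit on the 4 arrays compared. AHNAK2 (-1.16 ± 0.13), PPP1R10 (-1.02), SYNCRIP (-0.98) and COL1A2 (-0.90) were among the lowest, and the collagenase genes MMP13 and MMP1 were at -0.86 and -0.57. CXCL8 was at 0.33 ± 0.16, with its 2B4 control at background as at 6 h. The interferon-stimulated genes stood upward with 19 of 24 positive, IRF9 as named, IRF7 at 0.82 and IFI44L at 0.54 (camera adjusted p = 0.000428). On single arrays their 12 h median was 0.29 in 2B4 and 0.03 in 1E8, and the call was lost without the 2B4 12 h array (adjusted p = 0.152). Cholesterol synthesis with IDI1 at 0.44 (0.00209), metastasis suppressors with CD63 at 0.42 (0.0165), oxidative phosphorylation with NDUFC2 at 0.57 (0.0205), and adenosine receptors and ectonucleotidases with the AMP hydrolase NT5E at 0.39 (0.0389) stood upward too. NDUFC2 was under the limit on both control arrays, so its value rests on controls at background. The adjusted p of these 5 lists was 0.582 or higher with an estimated correlation. The other 19 had adjusted p from 0.0585 to 0.985, 4 of them with signs that differed, and adjusted over the list alone 4 members were higher and 3 lower. limma called 0 genes, with 292 higher and 724 lower at an unadjusted p under 0.05 (520 and 474 with arrays scaled to 1 median, 420 and 571 after quantile normalization) and a smallest adjusted p of 0.334. Without 1 array 24 genes (either 6 h array), 8 (2B4 control), 4 (1E8 control), 2 (1E8 12 h) or 0 (2B4 12 h) passed, and 3, 4, 4, 1 or 2 lists in that order. Adenosine receptors and ectonucleotidases lost their call in all 6 fits (adjusted p from 0.0706 to 0.235), oxidative phosphorylation in 5 (up to 0.215), metastasis suppressors in 3 (up to 0.201), and cholesterol synthesis (0.0608, without the 1E8 12 h array) and the interferon list in 1. TELO2 lay between 0.32 (without the 2B4 12 h array) and 1.61 (1E8 12 h), and MUC13 between 0.68 and 1.67 (likewise). Nearest to 0, PPP1R10 came to -0.61 (2B4 12 h), MMP13 to -0.51 and CXCL8 to 0.22 (1E8 control), IRF7 to 0.51 (2B4 12 h), NDUFC2 to 0.34 (1E8 12 h), and without the 2B4 control SCARNA13 came to 1.01, COL1A2 to -0.59, IFI44L to 0.31 and IDI1 to 0.12.

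Lower at 12 h than at 6 h were CXCL8 (12 h against 6 h, -1.22 ± 0.16), the histone variant H3F3B (-1.23 ± 0.19), TERC (-1.09 ± 0.13), the transcription termination factor PCF11 (-1.02) and the endoplasmic reticulum chaperone HSPA5 (-0.93). RAB26 (1.11 ± 0.18), CLIC3 (0.95), HIST2H4A (0.83), RPRML (0.79) and TELO2 (0.76) were higher at 12 h. Heat shock genes stood lower at 12 h in 17 of 18 members, with a median of -0.25 (camera adjusted p = 9.26e-07, and 0.651 as the adjusted p with an estimated correlation). G2/M genes stood lower in 33 of 44 (9.45e-05, and 0.891 with an estimated correlation as the adjusted p), and histones higher in 13 of 15 with a median of 0.26 (0.000321, and 0.762 with an estimated correlation as the adjusted p). limma called 0 genes between the times, with 368 higher and 402 lower at an unadjusted p under 0.05, and 6 genes without the 2B4 6 h array or 3 without the 1E8 6 h array. The other 21 lists had adjusted p from 0.0783 to 0.933, 3 of them with signs that differed, and adjusted over the list alone 4 members were higher and 4 lower. Without either 2B4 ATP array 5 lists were called. The G2/M call was lost without the 2B4 6 h array (adjusted p = 0.206), and the other 2 were kept without each array in turn. TELO2 lay between 0.12 (without the 2B4 12 h array) and 1.40 (1E8 12 h), and CLIC3 between 0.57 and 1.32 (2B4 6 h, 1E8 6 h).

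Set against the control array of its own subclone, the 1E8 6 h array had 57 genes at least 2-fold higher and 91 lower, and the 1E8 12 h array 36 and 57. The 2B4 arrays had 30 higher and 36 lower at 6 h and 41 and 34 at 12 h. These are differences between single arrays with no replicate check. In 1E8 at 6 h the polyamine oxidase SMOX was higher by a log2 of 1.98, and PCMTD1 and TRIM2 were at -1.38 and -1.21. With arrays scaled to 1 median the 1E8 splits turned to 80 higher and 55 lower at 6 h and 51 and 29 at 12 h, as that scaling moved the median of all genes on those pairs from -0.07 to 0.04 and from -0.08 to 0.04. With an offset of 50, 22 were higher and 7 lower in 1E8 at 6 h and 13 and 4 at 12 h. With no filter on dim entries these were 330 and 162, and 281 and 110, and with the limit passed on at least 3 arrays 42 and 47, and 29 and 20. More genes stayed lower in 1E8 after quantile normalization (54 higher and 87 lower at 6 h, 28 and 59 at 12 h), with values floored at 50 (34 and 52, 14 and 39), with the limit passed on all 6 arrays (18 and 26, 10 and 13) and at a 1.5-fold threshold (264 and 634, 179 and 627). Quantile normalization gave 41 higher and 32 lower in 2B4 at 6 h. In 2B4 at 12 h the split turned to 156 higher and 195 lower with no filter and 273 and 337 at a 1.5-fold threshold. It stayed at more genes higher with arrays scaled to 1 median (41 and 33) and after quantile normalization (52 and 30). Heat shock genes had a median of 0.23 in 1E8 and 0.21 in 2B4 at 6 h, at percentiles 99.97 and 99.98 of random lists, and -0.10 and -0.00466 at 12 h. The interferon list was highest in 2B4 at 12 h, with a median of 0.29 at percentile 99.99, and G2/M genes in 2B4 at 6 h, with 0.23 above all 10000 random lists. Across genes, which are not independent replicates, the 6 h responses of the subclones correlated at r = 0.20 (covariance 0.0192, simulated 5.46e-05), with 14 genes at least 2-fold higher in both against 0.154 for independent lists. The 12 h responses correlated at r = 0.06, with 3 genes higher in both against 0.133. Within a subclone 6 h and 12 h share their control array: r was 0.72 in 1E8 and 0.61 in 2B4, against 0.50 in simulated unchanged arrays, and the covariances were 0.0779 and 0.0529 against 0.0266. Part of that excess may come from the shared control. All 4 ATP arrays had the same sign for 28.1% of genes, against 22.3% simulated, with 1131 genes higher and 1986 lower. The simulated differences were centred on 0, while those of 1E8 had medians of -0.07 and -0.08. The surplus of lower genes may thus come from the array scale, and these counts were not repeated with another scaling.

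**Figure D3:**
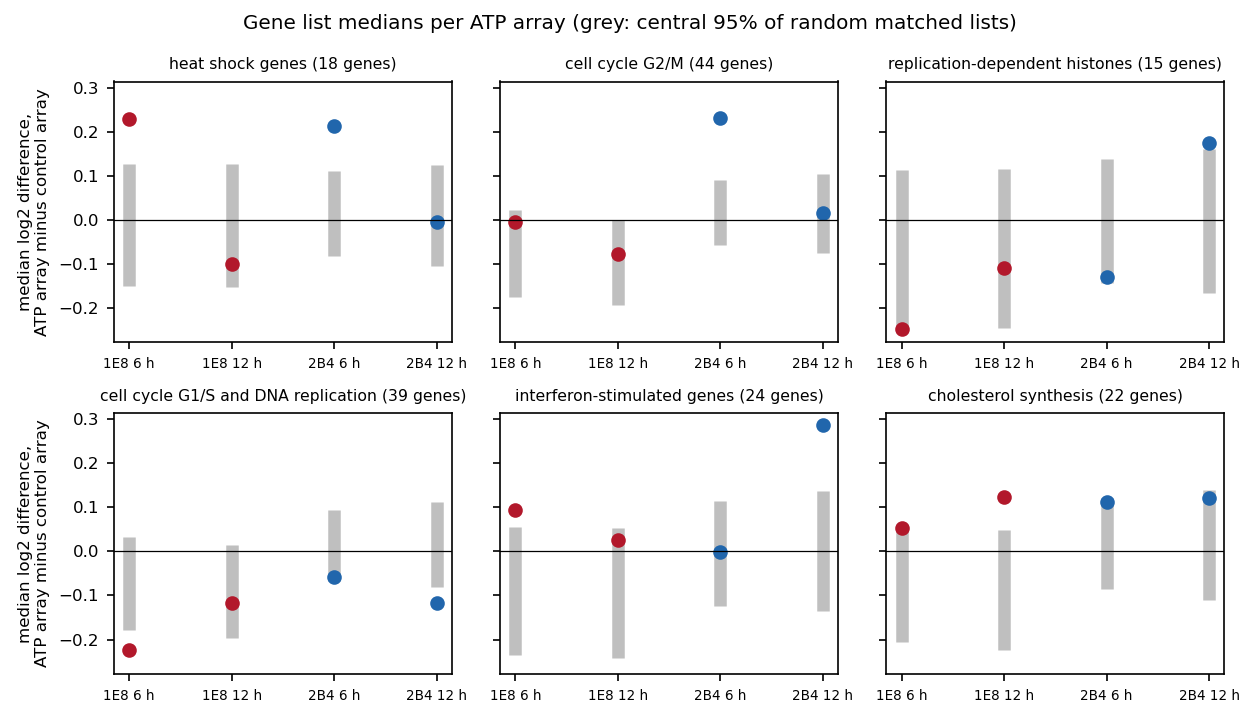
Median log2 difference between each ATP array and the control array of its subclone for 6 gene lists (points), with grey bars for the central 95% of 10000 random lists matched on mean expression. Heat shock medians lie above the bars at 6 h in both subclones (0.23 and 0.21) and within them at 12 h, and with arrays scaled to 1 median the fitted 12 h median of this list turns positive, from -0.05 to 0.01.

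The subclones differed far more from each other than from their ATP-treated cultures. The microseminoprotein MSMP was higher in 1E8, at a log2 of 12.3 ± 0.08 against 9.20 ± 0.14 in 2B4 (SD, n = 3 arrays, 1 per condition), a difference of 3.08 ± 0.10 (SE). The metastasis-associated calcium-binding protein S100A4 was higher by 2.36 ± 0.10, ANKRD30A by 2.20 ± 0.11 and the epithelial adhesion molecule EPCAM (deposited as TACSTD1) by 1.94 ± 0.15. PPIC, PRRX2, CKMT1A, ODZ3, ALDH1A1 and CD70 were higher by 1.54 to 1.93. The G protein regulator RGS4 was lower in 1E8, at -3.25 ± 0.16, and DYNLT3, ANXA10, ZNF365, PIR, S100P, FAM105A, VAT1, MGP and CCL26 followed at -1.94 to -1.61. limma called 1901 genes, 1019 higher in 1E8 and 882 lower, of which 165 and 144 were at least 2-fold, and the 20 named here had adjusted p of 4.31e-05 to 0.00113. With no filter on dim entries 0 genes passed (smallest adjusted p 0.0629) and with values floored at 50 there were 622. Without either 12 h array 921 passed and without either 6 h array 1145.

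Genes seen in a single subclone give bounds: 121 were above the limit on all 3 arrays of 1E8 and on none of 2B4, and 27 the reverse. The limit of the 1E8 control array was lower than the others, which makes it harder for a gene to lie under it, and with the highest limit of 52.6 on every array these counts were 117 and 72. The cancer-testis antigen MAGEA10 was at least 10-fold higher in 1E8 (adjusted p = 6.31e-06), CLRN3 at least 7.53-fold, the chemokine CXCL1 at least 4.36-fold, the glutamate transporter SLC1A3 at least 3.78-fold and SNRPN at least 3.62-fold. In 2B4, SHISA2 was at least 9.9-fold higher, the growth factor receptor PDGFRA at least 4.23-fold, MAOA at least 3.89-fold, CRISPLD2 at least 3.35-fold and SYTL4 at least 2.56-fold. For ATP such bounds were small. NDUFC2 and ASH1L, at least 1.36-fold and 1.2-fold brighter with ATP, were the only 2 genes above the limit on all ATP arrays and on no control, against 28 the reverse. With the highest limit on every array these counts were 12 and 15. The 28 were led by PAQR8 and RPPH1 at 1.39-fold. CCDC91, EPM2AIP1 and MLLT10 followed at 1.3, 1.26 and 1.21, and none of these passed in limma.

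**Figure D4:**
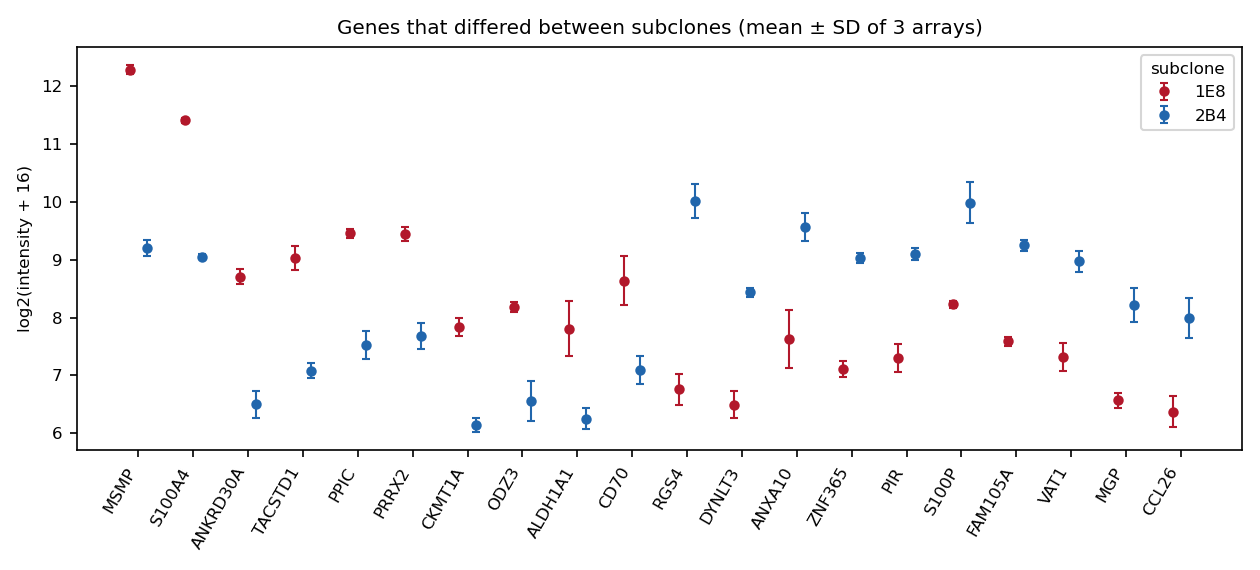
Mean log2(intensity + 16) of 20 genes in 1E8 and 2B4, with bars for the SD of 3 arrays (control, 6 h and 12 h of ATP). MSMP lies at 12.3 in 1E8 and 9.20 in 2B4, and RGS4 at 6.76 and 10.0.

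Between the subclones camera called 5 lists at the preset correlation and none with an estimated one. Of 17 NF-kB targets and cytokines tested, 9 were higher and 1 lower past the threshold, with CXCL8 higher by 2.09 ± 0.13, CXCL1 at least 4.36-fold and BCL3 at least 1.62-fold, and IL1B at least 2.17-fold lower (camera adjusted p = 0.000244). Of 24 interferon-stimulated genes 13 were higher and 1 lower, with IFITM3 at 1.29 ± 0.11 and ISG20 at 1.31 (0.000244). Of 15 epithelial junction genes 7 were higher and 1 lower, with CLDN3 at least 1.75-fold higher and the desmosomal cadherin DSC2 lower at -1.03 (0.024). Of 15 replication-dependent histone genes, 10 were lower in 1E8 and 0 higher, with HIST2H2BE at -1.14 and HIST1H4H at -0.92 (2.53e-06). Of 22 cholesterol synthesis genes 5 were lower and 1 higher, with NSDHL at -0.69 and LSS at -0.66 lower and TM7SF2 higher at 0.99 (0.03). The adjusted p of these 5 lists was 0.648 with an estimated correlation. Cholesterol synthesis lost its call without either 6 h array (adjusted p = 0.17), and the other 4 kept theirs without each array in turn. Adjusted over the list alone, 9 NF-kB, 13 interferon and 9 junction genes were higher, and 11 histone and 6 cholesterol genes lower. The other 19 lists had adjusted p from 0.0841 to 0.806, and 3 of them, such as the proteases with a median of 0.05 and a downward test, had signs that differed. Among mesenchymal genes 4 were higher and 4 lower, with S100A4 (2.36) and COL1A2 (1.37) higher, AXL at least 1.27-fold higher, and CDH11 lower (adjusted p = 0.000159). CDH11 was above the limit on all 3 arrays of 2B4 and 1 of 1E8. Among protease genes PLAT (1.12) and PLAU (0.81) were higher and the inhibitor TIMP1 (-0.95) lower, and among metastasis suppressors CD9 was higher (1.96) and ARHGDIB lower (-2.84 ± 0.17). The ectonucleotidase NT5E was lower in 1E8 by a log2 of -1.32 ± 0.11. With the limit passed on at least 3 arrays, 3 lists were called.

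The response to ATP differed between subclones for 1 gene in limma, the uncharacterized LOC100132761, with a difference of 3.23 ± 0.19 and an adjusted p of 0.0409. It lies outside the naming rule and was chosen after its values were seen. Its intensity was 38.1 in the 1E8 control and 278 and 304 with ATP, and 272 in the 2B4 control and 163 and 155 with ATP. Of the genes the rule names, PRIM2 (1.48), PPID (1.46), the inhibitor of differentiation ID1 (1.29), NOL10 (1.26) and the circadian regulator CLOCK (1.11) had more positive responses in 1E8. The myosin light chain MYL12A (-1.27), RNASEH2B (-1.23), RPL31P10 (-1.23), LRRFIP1 (-1.22) and BMP6 (-1.22) had more negative ones, and the adjusted p of these 10 lay between 0.107 and 0.151. At an unadjusted p under 0.05 there were 614 genes above 0 and 1481 below, against 1102 and 831 with arrays scaled to 1 median and 731 and 1129 after quantile normalization. No list was called, with adjusted p from 0.114 to 0.974, and 9 of 24 had a median, mean and test that differed in sign, while with no filter on dim entries 1 list was called downward (adjusted p = 0.00624). The number of genes called ranged from 0 to 741 over the alternatives.

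Of the P2 receptors, P2RX4, P2RY2 and P2RY11 were above the limit on at least 1 array, and none was on all 6. P2RY11, higher at 6 h, was the 1 of these 3 with a negative value at 12 h. Adjusted over the list alone, it was lower at 12 h. P2RX4 was at 0.24 ± 0.13 with ATP (adjusted p = 0.581) and P2RY2 was above the limit on 1 array of 1E8. Its subclone difference passed in limma (adjusted p = 0.0068) but came to 0 with values floored at 50. P2RX7 reached at most 2.94, below every limit. SNAI1, CDH1 and MMP3, named in advance, were above the limit on no array, with highest intensities of -10.9, 19.0 and 38.4. CLDN1 was above the limit on 2 arrays of 1E8 and none of 2B4, with 94.8 in the 1E8 control and 82.0 and 36.2 with ATP. MMP13 was at -0.81 ± 0.18 with ATP (adjusted p = 0.248), MMP1 at -0.46 ± 0.13 (0.335) and MMP11, above the limit on 1 array, had an adjusted p of 0.606. Without the 1E8 control the value of MMP13 was -0.46.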

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

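The tests on scaling, on all short noncoding RNAs and on the members without a host gene were chosen after the results were seen, the scaling tests were narrowed after their first outcome, and the weak-signal test was set in advance but read against a further scaling after its outcome. The ATP responses of the subclones differed in limma for LOC100132761, by a log2 of 3.23, and its adjusted p ranged from 1.44e-07 to 0.281 over the alternatives. The ATP responses at 12 h and 6 h differed in camera for heat shock genes (median -0.247), G2/M genes (-0.187) and replication-dependent histones (0.262), with adjusted p of 0.651 or higher for each once the correlation was estimated, and the G2/M difference was not called without the 2B4 6 h array (adjusted p = 0.206).

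10 short noncoding RNAs, 7 of them SCARNA, were higher on all 4 ATP arrays by at least 0.7 in the ATP contrast, with a median of 1.52. That median was 0.838 in 1E8 and 2.15 in 2B4. Of the 10, 5 were under the limit on both control arrays and so were tested only through ATP arrays. Without the 2B4 control array the fit returns the 1E8 value of 0.838, since 2B4 then adds nothing to the contrast. That fit therefore cannot tell whether the larger value in 2B4 comes from its control array or from its ATP arrays. A better recovery of all short RNAs from the ATP cultures is argued against by the 95 tested, these 10 included, which had a median of -0.108 with an SD of 0.547, and by the 34 SNORA and 37 SNORD entries, with medians of -0.111 and -0.166. A recovery limited to SCARNA stays open. The authors' scaling is argued against by a median of 1.52 for the 10 after quantile normalization and 1.57 with arrays scaled to 1 median, although values floored at 50 bring it to 0.76. More RNA of the host genes is argued against for 7 of them by a median of 0.0184 over the genes that overlap them, the highest being SNHG10 at 0.446, while the other 3 have no tested overlapping gene and stay open. An ATP response of these RNAs stays open too, as does a change in the poly(A) tails from which the labelling primes. Neither was tested or is backed by a call in limma, and measuring these RNAs without priming from poly(A) tails would decide between them.

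On the 1E8 arrays 61.5% of the genes at least 2-fold apart at 6 h were lower with ATP. With arrays scaled to 1 median the share was 40.7% and after quantile normalization 61.7%. These scalings point opposite ways, so the authors' scaling may account for the excess and cannot be told apart from an ATP response. The filter on dim entries stays open too. Of the 6 arrays, the 1E8 control had the lowest limit, 29.6, and the most tested entries above it, 10819. With no filter 330 genes were 2-fold higher and 162 lower at 6 h. With the limit passed on at least 3 arrays these were 42 and 47, and on all 6 arrays 18 and 26. More genes stayed lower in each of these. Weak signals on the 1E8 control array, whose background was the narrowest, stay open. Among the 5180 genes with a mean intensity of at least 200, 74.2% of those at least 1.5-fold apart were lower, which counted against weak signals by the bound set in advance. That bound took the deposited scale for granted: the share was 35.3% with arrays scaled to 1 median, and with an offset of 50, which damps dim entries, 22 genes were 2-fold higher and 7 lower. A loss of RNA under ATP specific to 1E8 stays open and was not tested.

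The 1901 subclone genes were set against the other ways to divide the 6 arrays into 3 and 3. Of the 10 splits 1 gave as many, the real one, and the highest of the others gave 0 genes. With 10 splits the share cannot fall under 0.05. Subclone is the only difference the labels give between these groups, and separate cultures or array batches of each subclone were not tested.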

How the results depend on the processing

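Quantile normalization, values floored at 50, the limit passed on all 6 arrays and the highest limit on every array were added after the data were seen. No paired analysis was possible because the groups share a single replicate number, 1, while subclone, which sets each ATP array beside its own control, is already a term of the model. Background correction of signals that were not normalized was planned and not run, because their columns match no label, and the deposited matrix, planned as an alternative, became the main source. The interaction has no residual degrees of freedom once an array is left out, so it has no such value. No list that was called, and no gene followed over these fits, turned to the opposite direction, although 3 values came to 0: P2RY2 between subclones and DUSP4 at 6 h with values floored at 50, and CLDN1 with ATP without the 1E8 control. Medians of lists that were not called did turn, such as that of heat shock genes at 12 h from -0.05 to 0.01 with arrays scaled to 1 median and that of junction genes with ATP from -0.02 to 0.04. Of the values for single genes 1274 kept their side of the threshold, 36 moved past it and 66 fell short of it, and with an array left out 759 kept it and 63 moved past it, the lone sample of a condition being assumed to vary like the others. Of the values for lists 231 kept their call and 66 lost it, and 126 and 72 with an array left out. Cholesterol synthesis with ATP, heat shock genes at 6 h and between times, histones between times and between subclones, and the interferon and NF-kB lists between subclones kept their calls in all 14 alternatives at the preset correlation. Genes above the limit on few arrays enter or leave with the filter, and differences of dim genes change with the offset and the floor.

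Genes that responded differently in the subclones numbered 1, and 6 with arrays scaled to 1 median, 364 with an offset of 50, 41 with the limit passed on at least 3 arrays, 283 on all 6 arrays, 741 with a mean-variance trend, and 0 with no filter, with the mean of the entries of a gene, after quantile normalization and with values floored at 50. The cause was not tested. Subclone genes were 0 with no filter and 622 floored at 50, the cause of which was not tested, and 921 to 2569 with an array left out, where a condition with a single array adds nothing to the contrast. Genes at 6 h were 1 with a mean-variance trend. Leaving out an array gave 0 to 57 genes for ATP, 5 to 49 at 6 h, 0 to 24 at 12 h and 0 to 6 between the times, 5 to 9 lists for ATP and 5 for subclone. With an estimated correlation 0 lists were called for ATP and 0 for subclone, and with the limit passed on at least 3 arrays 3 for subclone.

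Genes at least 2-fold apart on the array pairs (1E8 6 h, 1E8 12 h, 2B4 6 h, 2B4 12 h) numbered 148, 93, 66 and 75. They were 29, 17, 16 and 21 with an offset of 50, which shrinks differences of dim genes, and 492, 391, 357 and 351 with no filter, which adds dim genes. With the limit passed on all 6 arrays they were 44, 23, 19 and 19, and on at least 3 arrays 89 and 49 in 1E8. Values floored at 50 gave 86 and 53 in 1E8 and 44 in 2B4 at 12 h, and a 1.5-fold threshold gave 898, 806, 503 and 610.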

Other observations

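The tests here were fixed in advance, and the lists shown were picked after their values were seen. Between subclones, the integrated stress list had 9 genes higher in 1E8 and 1 lower of 35, with the stress-induced mTOR inhibitor DDIT4 higher by 2.82-fold, NUPR1 at 0.79 and CEBPB at 0.62, and the hypoxia and glycolysis list 7 higher and 1 lower of 33, with the neuronal enolase ENO2 at least 2.26-fold higher and CA9 at 0.78. Neither list was called by camera (adjusted p = 0.19 for both, and 0.648 and 0.765 with an estimated correlation). Of 8 basal and stem cell markers tested, 4 were higher and 1 lower, with ALDH1A1 at 1.56 and ALDH1A3 at 0.51 higher. That list was not called either (adjusted p = 0.553, and 0.765 with an estimated correlation), and its median of 0.185 came to -0.0693 with values floored at 50.

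Some genes known to restrain growth or to mark the prostate lineage had the same sign on all 4 ATP arrays without passing the threshold. The cell cycle inhibitor CDKN1A was higher by 0.68 ± 0.16 (adjusted p = 0.279), while the list of 15 p53 targets had a median of -0.00679 (adjusted p = 0.733). The homeobox gene HOXB13 was at -0.52 ± 0.12 (0.264), while its list of 8 luminal and androgen response markers had a median of -0.0174 with 3 positive (adjusted p = 0.956). Of the markers of other cell types, 4 leukocyte and 4 fibroblast or endothelial genes were tested, too few for camera, with ATP medians of 0.16 and 0.0042. No gene passed over all genes, and adjusted over the list alone 1 fibroblast or endothelial gene was higher and 1 lower.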
